A study of Mus musculus with 6 samples.

How the data were processed

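Total RNA from 6 mouse samples was labelled with biotin and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, a 1-colour design, per the labels' protocols. Lymphoma cells were enriched by depletion with CD43 beads and were at least 95% positive for B220 and GFP by flow cytometry, per the labels. The premalignant cells are described as sorted splenic B cells. The characteristics call them normal control cells, while their titles and source name them as premalignant Eµ-Myc cells, and the latter description was used.

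The authors deposited 1 normalized value per probe set. The deposited log2 values had been normalized and summarized by the authors. They ranged from about 2.3 to 14.2, and the log2 scale was inferred from the values. The background correction, normalization and summarization methods were not given in the sources used here. Array medians over all probe sets lay between 6.75 and 6.91 and were close but not identical, so offsets of that size between arrays remain in the differences. Signal over background limits what can be seen for genes near the floor, and the number of arrays limits precision.

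Of 35512 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12102 had none. The last 2 kinds were not named and not used in the gene analysis, except for a count of those called. Of the probe sets with 1 symbol, 21698 had an Entrez identifier found in the reference gene table (GRCm38.p6), and no symbol changed. For the 999 genes with more than 1 probe set, the one with the highest mean signal was used, which gave 19938 genes. Chromosomes came from the same table; no build was named for the array values, so no coordinates are given. Cdkn1a shares its probe set with another gene and Trp53 was not analysed here.

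The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (no intercept, no covariates), with empirical Bayes moderation (8.51 prior and 3 residual degrees of freedom). The contrasts were the mean of the hairpin groups minus premalignant cells, each hairpin minus premalignant cells, and shEzh2.781 minus shEzh2.556. P-values were adjusted by Benjamini-Hochberg over all genes, and genes were called at 0.05. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists, with camera at an estimated correlation and fry as alternatives. The estimated correlation rests on the 3 residual degrees of freedom, which leaves that alternative little power. The lists, which included markers of other cell types, were fixed before the data were examined, as were the tests and the alternatives except where stated. Of 828 listed symbols 739 were measured under the listed symbol, and 3 were matched through an older symbol to another gene (Gpi1 to Pigq in 2 lists and H19 to Nckap1), a matching fault found after the tests. The 742 were kept in the main test, and the lists were tested again without these 3. Marker lists of salivary gland secretory, glandular epithelial, eosinophil, further neutrophil and further erythroid genes were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

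The genes named were chosen by a rule. Predicted genes, immunoglobulin and T cell receptor segments, olfactory and vomeronasal receptors, small RNAs and the sex-linked list were left out of the ranked parts. These took the 10 largest rises and 10 largest falls in lymphomas among called genes with all 4 lymphoma arrays on one side of both premalignant arrays, and the 6 largest in each direction between hairpins among called genes whose arrays did not overlap. In each list up to 4 members with the smallest p could be named, and any list member where its list is described. Ezh2, Ezh1, Eed, Suz12, Cdkn2a, Cdkn1a, Trp53, Mdm2, Myc, Bcl2 and Bcl6 were always to be given. By this measure 2525 genes had all 4 lymphoma arrays above both premalignant arrays and 3211 had them below. Chance gives 13.3% of genes for both directions together.

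The fit was tested on simulated arrays of 19938 genes with 200 changed genes, 20 times per comparison. With variances drawn from the fitted prior, changes of 0.5, 1 and 2 (log2) were recovered in 43.7%, 99.1% and 100% of cases for lymphomas against premalignant cells, in 21.3%, 96.4% and 99.9% for shEzh2.781 and in 21.4%, 97.2% and 100% for shEzh2.556 against premalignant cells, and in 20.4%, 97% and 100% between hairpins. False calls made up 5.22%, 6.19%, 4.84% and 4.8% of calls in these 4 comparisons. With each gene's own moderated variance in place of drawn ones, false calls made up 9.16%, 9.89%, 8.56% and 9.15%, above the nominal level. A list shifted by -0.3, that of mitosis genes, was called in 20 of 20 simulations, with 11 calls of unshifted lists over all 20. The simulated genes varied independently, so these runs could not test the preset correlation of 0.01. In the data the estimated correlation was 0.524 for the mitosis list. It ranged from -0.0626 for MHC class I to 0.866 for megakaryocyte and platelet markers.

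The alternatives were quantile normalization, arrays shifted to one median, genes above the median level only, a variance trend with robust moderation, array weights, the mean of all probe sets of a gene, the replicate number as a block, a minimum change of 2-fold, each array left out in turn, a fit with the 4 lymphomas as one group, and fits of the 2 groups compared alone. No 2 arrays held the same values: at most 11 probe sets were equal to all decimals between any pair.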

Results

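Gene expression was measured in B cells of Eµ-Myc mice, a lymphoma model in which an immunoglobulin heavy chain enhancer drives the Myc oncogene in the B lineage. The 6 arrays fell into 3 groups of 2. One group held sorted premalignant splenic B cells from 2 independent preparations. The others held primary lymphomas carrying a short hairpin RNA against Ezh2, the histone H3 lysine 27 methyltransferase of polycomb repressive complex 2, with shEzh2.781 in one group and shEzh2.556 in the other. The labels do not say that the 2 lymphoma arrays of a hairpin came from separate mice, so the p-values measure the spread between these samples, which may be partly technical. No lymphoma without an Ezh2 hairpin was analysed here, so malignancy and the hairpin could not be separated in the comparisons with premalignant cells. The lymphoma cells were enriched by CD43 bead depletion and the premalignant cells were sorted. The way the cells were prepared could therefore not be separated from either in these comparisons, including those of B-lineage genes. Signals were deposited on a scale read as log2, and differences are given in log2 units with the standard error (SE) of the limma fit. The number of arrays limits the precision.

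The first comparison looked at Ezh2, the target of the hairpins. Without a lymphoma free of an Ezh2 hairpin, a lower Ezh2 signal could not be assigned to the hairpins. Ezh2 signal was 12.67 ± 0.05 (SD, n = 2) in premalignant cells, 10.99 ± 0.11 (SD, n = 2) in shEzh2.781 lymphomas and 11.25 ± 0.07 (SD, n = 2) in shEzh2.556 lymphomas. It was lower in 4 of 4 lymphoma arrays than in both premalignant arrays. Ezh2 fell by 1.68 (SE 0.11, limma adjusted p = 3.43e-06) with shEzh2.781 and by 1.42 (SE 0.11, adjusted p = 6.74e-06) with shEzh2.556, and over both hairpins it was 2.92-fold lower (adjusted p = 1.31e-06). The difference between hairpins was -0.26 (SE 0.11, adjusted p = 0.151). Of the other subunits of the complex, Eed differed by 0.09 (SE 0.11, adjusted p = 0.676) and Suz12 by -0.23 (SE 0.09, adjusted p = 0.144) between all lymphomas and premalignant cells. Suz12 fell by 0.39 with shEzh2.556 (adjusted p = 0.0272). Ezh1, the paralogous methyltransferase, differed by -0.04 (SE 0.10, adjusted p = 0.86), a value that was 0.0056 after quantile normalization. Myc differed by 0.14 (SE 0.09, adjusted p = 0.402).

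**Figure D1:**
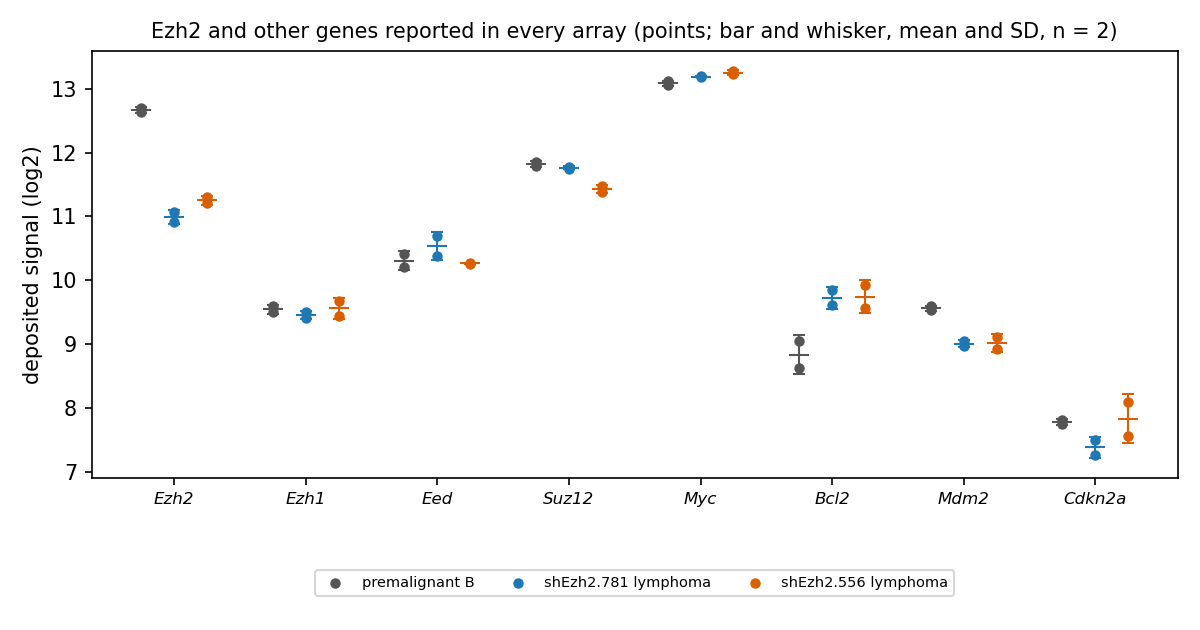
Deposited log2 signal (vertical axis) of 8 genes in the 6 arrays; points are arrays, and the bar and whisker are the mean and SD of the 2 arrays of a group. The Ezh2 means lie at 12.67 in premalignant cells and at 10.99 and 11.25 in the lymphomas, while the Myc means lie between 13.08 and 13.25.

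Lymphomas of both hairpins were then compared with premalignant cells, to ask what distinguished the malignant, Ezh2-targeted cells. The largest rises included Cpn1, the catalytic subunit of carboxypeptidase N, which rose by 5.85 (SE 0.10, adjusted p = 2.28e-11) and reached about the same level in all lymphoma arrays. Hepacam2, an adhesion molecule, rose by 4.56 (SE 0.12), the forkhead factor Foxf2 by 4.35 (SE 0.11), Ccdc180 by 3.68 (SE 0.19) and Apobec2 by 3.17 (SE 0.12), with adjusted p at or below 2.91e-07 for each. Of the 10 largest rises, 4 encode proteins of saliva or of related secretions. Mucl2 rose by 4.81 (SE 0.22), Bpifa2 by 4.26 (SE 0.24), Prol1 by 3.44 (SE 0.15) and Dcpp3 by 3.42 (SE 0.33), and each was at least 3.87 higher with shEzh2.556 than with shEzh2.781.

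Among the largest falls, Igll1, which encodes a surrogate light chain component of pre-B cells, fell by 3.79 (SE 0.27, adjusted p = 3.15e-06), and the transcription factor Lef1 fell by 3.09 (SE 0.11, adjusted p = 1.18e-08). The DNA demethylation enzyme Tet1 fell by 2.88 (SE 0.10), Marcks by 2.91 (SE 0.12), Hook1 by 2.97 (SE 0.10) and Tspan6 by 3.12 (SE 0.14), and Tes differed by -2.85 (SE 0.10). The remaining 3 are genes of eosinophils and platelets. Ear6 fell by 3.76 (SE 0.09), Prg2 by 2.88 (SE 0.10) and Ppbp by 3.23 (SE 0.27). In all, 1117 genes were higher and 1916 lower among 19938 tested, and 197 and 320 of these changed at least 2-fold. The count of 3033 was 1972 without premalignant array 1, 1721 without premalignant array 2, and 1091 when the 4 lymphomas were fitted as one group.

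**Figure D2:**
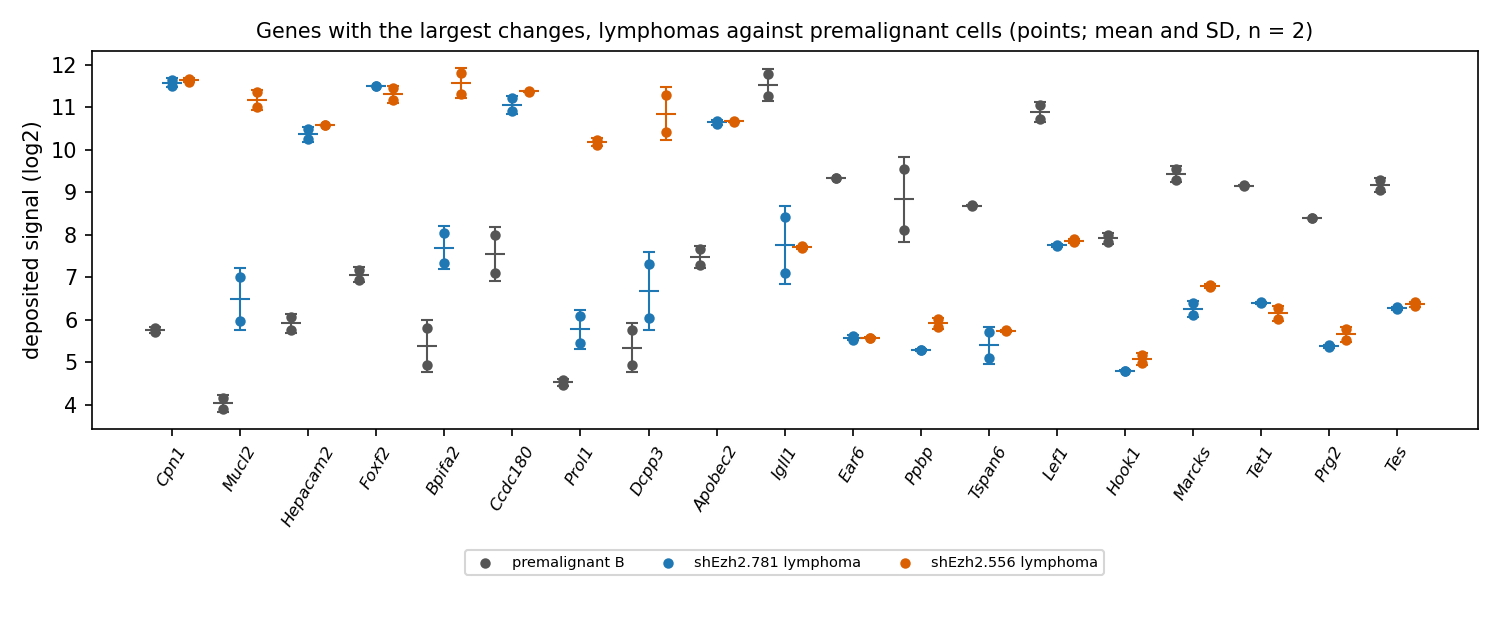
Deposited log2 signal (vertical axis) of 9 of the 10 genes with the largest rise and the 10 with the largest fall in lymphomas against premalignant cells; points are arrays, and the bar and whisker are the mean and SD of 2 arrays. Cpn1 lies near 5.8 in premalignant cells and near 11.6 in all lymphomas, whereas Mucl2 lies at 11.35 and 11.01 with shEzh2.556 and at 7.01 and 5.96 with shEzh2.781.

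Lists of B-lineage genes were called lower in the lymphomas at the preset correlation. Of 23 measured pro-B and pre-B cell genes, 17 fell and 1 rose (18 fell adjusted over the list alone; camera adjusted p = 2.48e-14, and adjusted p = 0.441 with an estimated correlation). Dntt, the terminal transferase of V(D)J recombination, fell by 2.64 (SE 0.16), Rag2 by 1.65 (SE 0.11) and Enpep by 2.01 (SE 0.11). Without premalignant array 2 the count that fell was 10. Of 22 genes expressed through most of the B lineage, 7 fell and 2 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.00476, and adjusted p = 0.532 with an estimated correlation). Bach2 fell by 1.17 (SE 0.10) and Cd72 by 1.25 (SE 0.11), while Bank1 rose by 1.43 (SE 0.16). All 3 immunoglobulin constant region genes measured fell (3 adjusted over the list alone; adjusted p = 2.26e-05, and adjusted p = 0.441 with an estimated correlation), among them Ighm by 2.06 (SE 0.29) and Igha by 2.46 (SE 0.27). Markers of neutrophils moved the same way as these groups, with a median change of -1.88.

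Mitosis genes were also lower, while few DNA replication genes passed. Of 39 mitosis genes, 28 fell and none rose (35 fell adjusted over the list alone; camera adjusted p = 8.12e-16, and adjusted p = 0.441 with an estimated correlation), with Cenpf falling by 0.87 (SE 0.13) and Kif4 by 0.69 (SE 0.11). This count was 11 without premalignant array 1, 13 without premalignant array 2 and 17 without shEzh2.556 array 1. Neutrophil and erythroid markers moved the same way, with medians of -1.88 and -1.01. Of 45 DNA replication genes, 5 fell (5 adjusted over the list alone; camera adjusted p = 0.0028, and adjusted p = 0.532 with an estimated correlation), and the list's call ended without premalignant array 1 (adjusted p = 0.319). The count of 5 was 2, 3, 3 and 3 without premalignant array 1, premalignant array 2, shEzh2.781 array 2 and shEzh2.556 array 1. With shEzh2.781 alone the replication list had a median of 0.0031 with 2 genes lower (adjusted p = 0.701), and with shEzh2.556 one of -0.24 with 11 lower (adjusted p = 3.05e-07, and adjusted p = 0.512 with an estimated correlation). E2f2 fell by 0.80 (SE 0.10). Of 6 cyclin-dependent kinase inhibitors measured, 3 fell and 1 rose (3 and 1 adjusted over the list alone). Cdkn2c fell by 1.10 (SE 0.10), Cdkn2d by 0.86 (SE 0.12) and Cdkn1b by 0.54 (SE 0.10). Cdkn2a, which encodes p16 and p19Arf, differed by -0.18 (SE 0.14, adjusted p = 0.476).

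Lists of growth genes were called higher at the preset correlation, although most of their members did not pass the test alone. Of 48 ribosome biogenesis genes that MYC induces, 8 rose and none fell (8 adjusted over the list alone; camera adjusted p = 1.11e-07, and adjusted p = 0.441 with an estimated correlation; median 0.19). Rcl1 rose by 0.47 (SE 0.10) and Wdr12 by 0.46 (SE 0.11), and the count of 8 was 4, 0, 5, 4 and 3 without premalignant array 1, premalignant array 2, shEzh2.781 array 1, shEzh2.781 array 2 and shEzh2.556 array 2. Of 29 genes measured for the metabolic MYC targets, 4 rose (7 adjusted over the list alone; adjusted p = 0.00779, and adjusted p = 0.441 with an estimated correlation), with the folate carrier Slc19a1 rising by 0.66 (SE 0.10), and 1 rose without either premalignant array. Of 20 genes measured for glycolysis, 6 rose and 1 fell (7 and 3 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.441 with an estimated correlation), and the glucose transporter Slc2a1 rose by 0.66 (SE 0.11), while 3 rose without premalignant array 2. In both lists the symbol Gpi1 had been matched to Pigq, a gene of glycolipid anchor synthesis, which was not called; without it the adjusted p was 0.00546 for 28 metabolic genes and 0.0102 for 19 glycolysis genes, with the same counts called. The metabolic and glycolysis calls ended without premalignant array 2, with adjusted p of 0.0818 and 0.0572. None of 30 ribosomal protein genes passed the test alone (0 adjusted over the list alone), although the list was called higher (adjusted p = 0.0118, and adjusted p = 0.635 with an estimated correlation; 0.148 after quantile normalization, 0.378 without premalignant array 2 and 0.078 without shEzh2.781 array 2).

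Lists of signalling and MHC class II genes were called lower at the preset correlation, with part of their members passing the test, and 1 of 12 MHC class I presentation genes fell. Of 29 interferon response genes, 16 fell (22 adjusted over the list alone; camera adjusted p = 3.15e-10, and adjusted p = 0.441 with an estimated correlation), including Ddx58 by 1.25 (SE 0.12) and Irf7 by 0.80 (SE 0.10), and 8 fell without premalignant array 2. Of 25 immediate-early genes of B cell activation, 12 fell (14 adjusted over the list alone; adjusted p = 3.09e-05, and adjusted p = 0.532 with an estimated correlation), with Dusp1 falling by 1.30 (SE 0.20) and Zfp36 by 1.01 (SE 0.11); 6 fell without premalignant array 2. Of 21 NF-kB targets, 6 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.014, and 0.116 without premalignant array 2; adjusted p = 0.532 with an estimated correlation). Tnfaip3, an inhibitor of this pathway, fell by 1.45 (SE 0.12). Of 9 MHC class II genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0054, and 0.0739 without premalignant array 1; adjusted p = 0.532 with an estimated correlation), and their regulator Ciita fell by 1.03 (SE 0.13). The 6 were 2, 1 and 3 without premalignant array 1, premalignant array 2 and shEzh2.556 array 1. Neutrophil and dendritic cell markers were lower alongside these lists, with medians of -1.88 and -0.40, the latter -0.23 without premalignant array 2. In the BCL2 family, which was not called as a list by any of these tests, Bcl2 rose by 0.90 (SE 0.14, adjusted p = 0.00121) and Bcl2l1 fell by 1.07 (SE 0.11, adjusted p = 3.87e-05). The p53 regulator Mdm2 fell by 0.55 (SE 0.10, adjusted p = 0.00276), and Bcl6 differed by -0.28 (SE 0.14, adjusted p = 0.238).

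Several lists of markers of other blood cells were called lower in the lymphomas, but not that of macrophages and monocytes, with 6 of 23 genes higher, 3 lower and a median of 0.09. The 6 and 3 were 2 and 4 without premalignant array 1, 3 and 2 without premalignant array 2, 3 and 4 without shEzh2.781 array 2, and 2 and 4 without shEzh2.556 array 1. Of 18 neutrophil markers, 17 fell (18 adjusted over the list alone; camera adjusted p = 7.93e-19, and adjusted p = 0.441 with an estimated correlation), with Ltf falling by 2.70 (SE 0.19) and Ly6g by 2.35 (SE 0.19). Of 11 erythroid markers 9 fell (10 adjusted over the list alone; adjusted p = 1.64e-08, and adjusted p = 0.441 with an estimated correlation), and 5 fell without premalignant array 2. All 11 were lower with shEzh2.781 (median -1.69) and 0 of 11 passed with shEzh2.556 (median -0.37), although the list was called lower there as well (adjusted p = 0.0459, and adjusted p = 0.696 with an estimated correlation). Of 8 megakaryocyte and platelet markers 4 fell (7 adjusted over the list alone; adjusted p = 2.26e-05, and adjusted p = 0.494 with an estimated correlation), and 7 fell without premalignant array 1. Of 16 NK cell markers 8 fell (9 adjusted over the list alone; adjusted p = 0.000442, and adjusted p = 0.441 with an estimated correlation), and 5 and 4 fell without premalignant arrays 1 and 2. Of 14 dendritic cell markers 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.00143, and adjusted p = 0.532 with an estimated correlation), among them Siglech by 2.74 (SE 0.20), and 4 fell without premalignant array 2. Of 20 T cell markers 5 fell and 1 rose (5 and 2 adjusted over the list alone; adjusted p = 0.0436, and adjusted p = 0.639 with an estimated correlation), with 3 falling without premalignant array 2; the call ended without premalignant array 2 (0.131), shEzh2.781 array 1 (0.0908) or shEzh2.556 array 1 (0.0614).

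In this comparison 19 of 34 lists were called, 4 higher and 15 lower. With an estimated correlation in place of the preset one, none was called by camera. The 19 lists had adjusted p = 0.441 to 0.639 with an estimated correlation, and 1 of the 34 had an unadjusted p under 0.05. With 3 residual degrees of freedom this version could hardly call a list, so a missing call says little. Even the neutrophil list, with 17 of 18 genes lower, had an unadjusted p of 0.0626 by camera with an estimated correlation. The rotation test fry, which does not compare a list with other genes, called 11. Of these, 8 were also called by camera, and the other 3 were PRC2 (fry adjusted p = 0.0408), the CDK inhibitors (0.0301) and MHC class I (0.0361), all lower. The PRC2 list holds Ezh2, the target of the hairpins. Ezh2 was the only 1 of its 12 genes called lower, and 1 was called higher (3 and 1 adjusted over the list alone). Some of the 19 lists were not called by camera with 1 hairpin alone. With shEzh2.781 these were DNA replication (adjusted p = 0.701), B-lineage identity (0.13), MHC class II (0.118) and glycolysis (0.0592, and 0.035 without Pigq). With shEzh2.556 they were the metabolic MYC targets (0.217), NF-kB targets (0.139), ribosomal proteins (0.536) and T cell markers (0.393). Camera did not call the lists of polycomb subunits and targets over both hairpins. With shEzh2.556 alone, developmental regulators were called higher (adjusted p = 0.0143; 4 of 65 genes higher and 3 lower; adjusted p = 0.696 with an estimated correlation) and PRC1 lower (adjusted p = 0.00268, and adjusted p = 0.512 with an estimated correlation). With shEzh2.781 alone neither was called (0.679 and 0.754). The developmental regulators had low signal, with medians of 6.33 to 6.63 per array. Their median change with shEzh2.556 was 0.17, against 0.07 over all genes. Of all 19938 genes 1355 were called higher with shEzh2.556, so 4 of 65 was no excess. Over both hairpins the adjusted p was 0.208 for PRC2, 0.0561 for PRC1, 0.38 for Hox genes and 0.183 for other developmental regulators, although Cbx2 of PRC1 fell by 1.10 (SE 0.11) and Bmi1 rose by 0.85 (SE 0.11). PRC1 passed the threshold without premalignant array 2 (0.0256) or shEzh2.556 array 2 (0.0382), as did developmental regulators (0.0342 and 0.0483). The CDK inhibitors had an adjusted p of 0.0536, and of 0.0292 to 0.0444 without shEzh2.781 array 1, shEzh2.781 array 2 or shEzh2.556 array 1. Lists of p53 targets (0.164), the BCL2 family (0.631), mature B cells (0.62), MHC class I (0.27), plasma cells (0.781), fetal genes (0.243, and 0.183 without Nckap1, to which the symbol H19 had been matched), macrophages (0.387) and sex-linked genes (0.631) were not called by camera either. Germinal centre genes (0.135) and stromal markers (0.16) were called only without premalignant array 1 (0.0402 and 0.00596). Sex-linked genes gave 1.29e-05 without premalignant array 1 and 0.00239, in the other direction, without premalignant array 2.

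**Figure D3:**
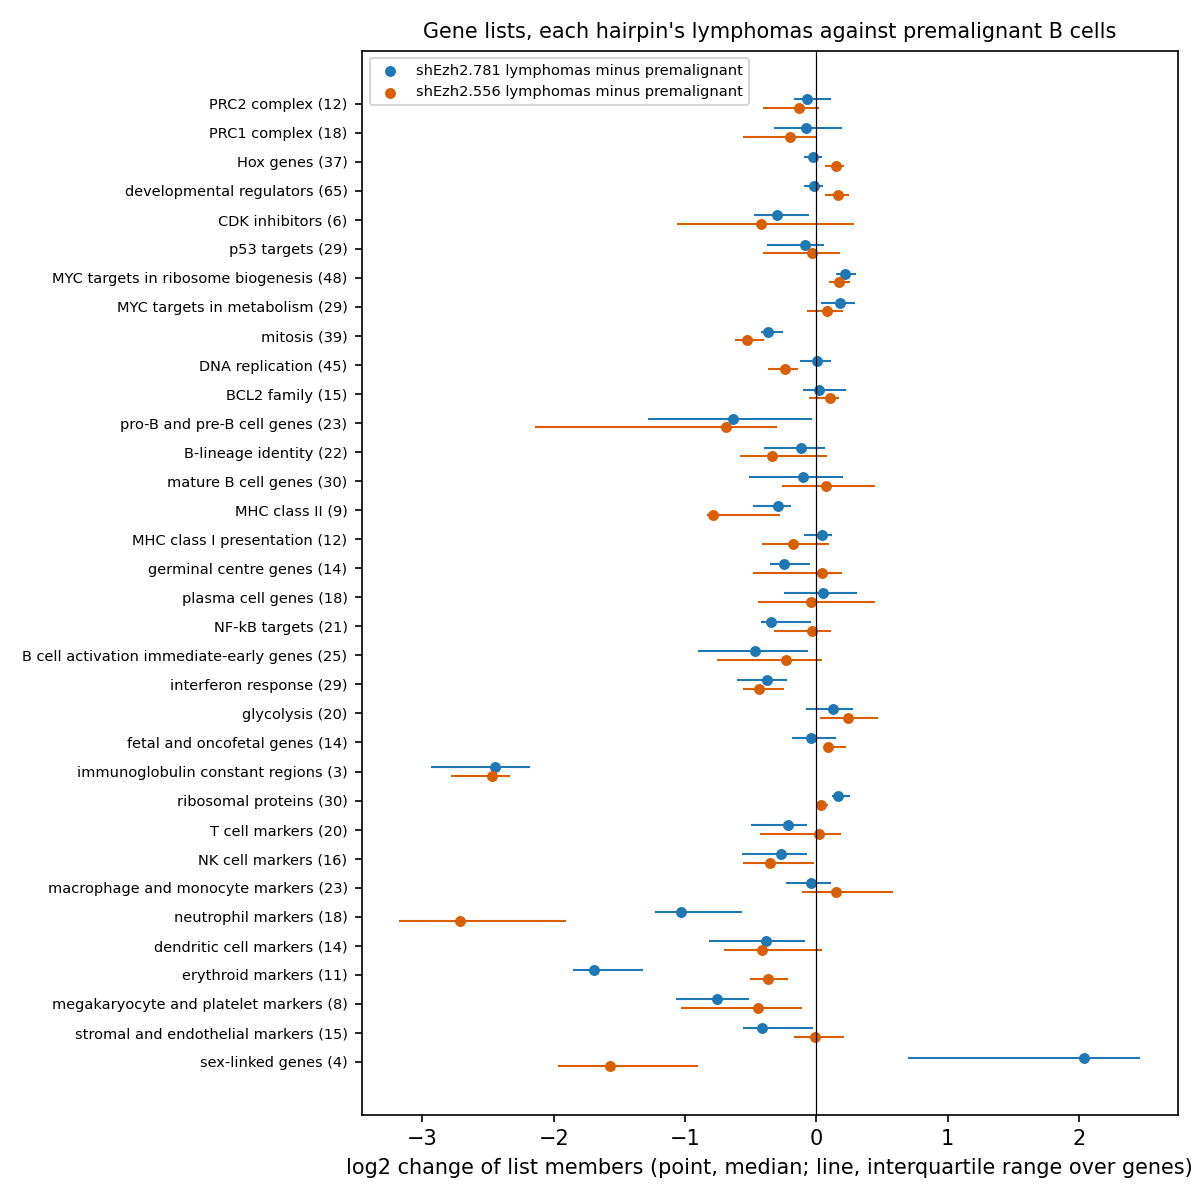
Median log2 change (points) and interquartile range over genes (lines) of each of the 34 gene lists, for shEzh2.781 and shEzh2.556 lymphomas against premalignant cells; the number of genes measured follows each name. The neutrophil list lies lower with shEzh2.556 and the erythroid list lower with shEzh2.781.

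Each hairpin was also compared with premalignant cells separately. With shEzh2.781, 917 genes were higher and 1244 lower, a split of 1206 and 894 when arrays were shifted to one median. With shEzh2.556, 1355 were higher and 2280 lower. The total for shEzh2.781 was 1103 without premalignant array 2, and that for shEzh2.556 was 2112 without premalignant array 1 and 1949 without shEzh2.556 array 1. Genes that changed the same way with both numbered 1411, of which 520 were higher and 891 lower, and 32 were called in opposite directions. Independent lists of these sizes would share 62.3 higher and 142 lower genes, and unchanged groups simulated against the shared premalignant arrays shared 0.32 on average over 50 simulations. The changes correlated across genes with r = 0.66, against 0.50 for simulated unchanged groups, and genes are not independent replicates. The covariance was 0.105, against 0.0085 simulated, a difference of 0.0965. The 2 controls are too few to split into parts of 2 arrays, so part of the excess may come from the shared controls. Without premalignant array 2 the shared count was 782.

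The hairpins' lymphomas were compared with each other to ask where the hairpins differed. Genes higher with shEzh2.781 included Egfl6, a secreted protein with EGF repeats, by 3.75 (SE 0.12, adjusted p = 9.85e-09), Mei4 by 2.98 (SE 0.16), the guanine nucleotide exchange factor Rasgef1a by 2.96 (SE 0.17), the zinc transporter Slc30a4 by 2.75 (SE 0.18), Fndc3c1 by 2.64 (SE 0.24) and the zinc finger factor Plag1 by 2.61 (SE 0.13). All 6 genes with the largest difference in the other direction encode secreted proteins of saliva or other glands. The carbonic anhydrase Car6 differed by -5.11 (SE 0.15, adjusted p = 6.45e-09), Dcpp2 by -4.997 (SE 0.40), Pip by -4.87 (SE 0.15), Dcpp1 by -4.80 (SE 0.24), Mucl2 by -4.69 (SE 0.26) and Scgb2b27 by -4.46 (SE 0.12). Altogether 1097 genes were higher and 903 lower with shEzh2.781, and 156 and 86 of these differed at least 2-fold. With arrays shifted to one median the split was 1913 and 405, so the balance of directions was not settled by the deposited scale. The total of 2000 was 1180, 1204, 718 and 953 without shEzh2.781 array 1, shEzh2.781 array 2, shEzh2.556 array 1 and shEzh2.556 array 2.

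Sex-linked transcripts separated the hairpins. Xist, expressed from the inactive X chromosome, was 8.89 ± 0.78 (SD, n = 2) with shEzh2.781 and 12.06 ± 0.15 (SD, n = 2) with shEzh2.556. The Y-linked gene Eif2s3y was 9.94 ± 0.15 (SD, n = 2) and 4.27 ± 0.13 (SD, n = 2), and Kdm5d and Uty differed the same way. In premalignant cells Eif2s3y was 4.15 in array 1 and 9.25 in array 2, with Xist at 12.24 and 11.14. Hairpin and sex could therefore not be separated between the hairpins. Without genes on chromosomes X and Y, an alternative chosen after the data were seen, 1959 genes were called.

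Neutrophil markers were higher with shEzh2.781 for 16 of 18 genes (17 adjusted over the list alone; camera adjusted p = 2.88e-19, and adjusted p = 0.722 with an estimated correlation; median 1.71), and erythroid markers were lower for 11 of 11 (11 adjusted over the list alone; adjusted p = 9.65e-10, and adjusted p = 0.722 with an estimated correlation; median -1.31). Cxcr2 was 2.32 higher (SE 0.28) and Car2 differed by -1.90 (SE 0.28), and 7 erythroid markers were lower without shEzh2.556 array 1. Of 45 DNA replication genes, 7 were higher with shEzh2.781 (12 adjusted over the list alone; adjusted p = 5.38e-10, and adjusted p = 0.722 with an estimated correlation), with Rfc3 differing by 0.96 (SE 0.15). That count was 1 without shEzh2.781 array 1 or shEzh2.556 array 1 and 2 without either other lymphoma array. Stromal and endothelial markers were lower for 2 of 15 genes (5 adjusted over the list alone; adjusted p = 0.00789, and adjusted p = 0.751 with an estimated correlation), with Acta2 differing by -1.37 (SE 0.16), and 1 was lower without either shEzh2.556 array. These 4 lists stayed called after quantile normalization, and the other 10 of the 14 called lists did not. Among genes of those 10 lists, the pre-B cell genes Bst1 and Il7r were 2.54 (SE 0.28) and 1.89 (SE 0.20) higher with shEzh2.781, Cd72 was 1.54 higher (SE 0.13) and Bmi1 was 1.18 higher (SE 0.13). Among the CDK inhibitors, not called as a list (adjusted p = 0.104), Cdkn2c was 1.20 higher (SE 0.11, adjusted p = 7.29e-05). The 14 lists had adjusted p = 0.722 to 0.757 with an estimated correlation, so none was called that way. Fry called none of the 34, and 1 had an unadjusted p under 0.05 by camera with an estimated correlation.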

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

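The tests of glandular epithelial genes and of further neutrophil genes were written before their results were seen; the other tests reported in this part were chosen after the pattern had been seen, and that of sex replaced an earlier one on premalignant array 1 alone after its result was seen. Groups of 2 arrays were too small to test single arrays for standing apart.

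A direct test of the hairpins against each other found 2000 genes that differed. Differences of shEzh2.781 minus shEzh2.556 (log2) were -4.69 for Mucl2, -3.87 for Bpifa2, -4.41 for Prol1, -4.18 for Dcpp3, -5.11 for Car6, -4.997 for Dcpp2, -4.87 for Pip, -4.80 for Dcpp1 and -4.46 for Scgb2b27. They were 3.75 for Egfl6, 2.98 for Mei4, 2.96 for Rasgef1a, 2.75 for Slc30a4, 2.64 for Fndc3c1, 2.61 for Plag1 and -0.55 for Marcks. Lists called by camera at the preset correlation, of which none was called with an estimated correlation or by fry and 4 stayed called after quantile normalization, had median differences of 0.22 for PRC1, -0.20 for Hox genes, -0.21 for developmental regulators, 0.13 for mitosis, 0.25 for DNA replication, 0.0532 for pro-B and pre-B cell genes, 0.16 for B-lineage identity, 0.50 for MHC class II, 0.22 for MHC class I, 0.12 for ribosomal proteins, -0.25 for macrophage markers, 1.71 for neutrophil markers, -1.31 for erythroid markers and -0.34 for stromal markers. The MHC class II difference came mainly from shEzh2.781 array 2. Relative to the premalignant mean, that list had medians of -0.59 and 0.0044 in shEzh2.781 arrays 1 and 2. In shEzh2.556 arrays 1 and 2 they were -0.69 and -0.77. In data the comparisons did not use, 639 probe sets without a gene symbol and 56 with several were called between lymphomas and premalignant cells.

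Of these, 10 genes of saliva and related secretions (Bpifa2, Car6, Pip, Prol1, Mucl2, Dcpp1, Dcpp2, Dcpp3, Scgb2b27 and Scgb1b27, picked for the pattern) were 4.73 to 7.15 higher in shEzh2.556 lymphomas than in premalignant cells, and 4 of them (Mucl2, Bpifa2, Dcpp3 and Prol1) were also called higher with shEzh2.781, by 1.24 to 2.46. Release of polycomb repression stays open: the median difference between hairpins was -4.58, but 6 of the 10 genes were picked as the largest such differences, so this value decides nothing. Sex stays open for the same reason: the 10 genes lay a median of 5.28 above the higher premalignant array, although both premalignant arrays carried Xist signal, but they were picked for being high with shEzh2.556. A candidate source is salivary gland tissue in the preparation. The 25 glandular epithelial genes had a median change of 0.31 with shEzh2.556 and of -0.02 with shEzh2.781, although 2 of the 25 were above 9 in premalignant cells. For shEzh2.556, 10000 matched random lists had a median of 0.12 and a 95th percentile of 0.19. With shEzh2.556, 9 of the 25 were called higher and 2 lower, and Epcam (0.07) and Cdh1 (-0.41) were not called. Krt18 rose by 0.88 with shEzh2.556 and by 0.90 with shEzh2.781. Against gland tissue stand the bead purification and the gate of at least 95% B220 and GFP. Other salivary genes were also low in the shEzh2.556 arrays, such as Amy1 at 5.87 and 5.75 and Smr3a at 5.82 and 5.24. Both were nevertheless called higher than in premalignant cells, by 0.61 and 0.58. Of the 14 salivary genes not picked for the pattern 4 were called higher, and an effect of shEzh2.556 alone was not tested.

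Neutrophil markers were lower with both hairpins, and erythroid markers were called lower in 11 of 11 genes with shEzh2.781 and in 0 of 11 with shEzh2.556 (12 and 4 of 21 further erythroid genes), where camera still called the list lower (adjusted p = 0.0459). A lower share of all non-B blood cells alike is argued against for the genes of the fixed lists. With shEzh2.781, 16 of 18 neutrophil markers were higher and 11 of 11 erythroid markers lower than with shEzh2.556. A common share would move both lists the same way. Between hairpins the neutrophil median of the fixed lists lay 3.01 above the erythroid median, against interquartile ranges of 0.84 and 0.64. This comparison was chosen after their medians had been seen, although the lists were not. For the further lists the gap was 0.55, within interquartile ranges of 0.58 and 0.75, so they leave the question open. Fewer neutrophils in the lymphoma preparations may account for the neutrophil part: 24 further neutrophil genes had a median change of -0.37, below the 5th percentile of matched random lists (-0.04), with 12 called lower and 2 higher, and 1 of the 24, Pglyrp1 at 9.14 and 9.23, was above 9 in both premalignant arrays. Ltf signal was 10.21 in premalignant cells, 8.42 with shEzh2.781 and 6.59 with shEzh2.556. Against fewer neutrophils in the lymphomas stands the sort of the premalignant B cells, which should leave few neutrophils to lose. The CD43 beads and the gate of at least 95% B220 and GFP were applied to the lymphomas and do not count against it. A change of transcription within the B cells stays open for both lists.

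Between the 2 shEzh2.781 arrays, genes of chromosome 15 had a median difference of 0.12 (array 1 minus array 2) and genes of chromosome 19 one of -0.14, while the largest absolute median of any other chromosome was 0.03. Noise or signal-dependent normalization is argued against, since 0% of 10000 random lists matched on level reached either difference. Single genes or a short segment are argued against as well, since 100% of the 10-megabase bins had the sign of their chromosome (9 of 9 and 6 of 6). Against the mean of the 4 arrays of the other groups, array 1 stood at 0.10 and -0.16 and array 2 at -0.03 and -0.02. A difference in chromosome number in part of the cells of array 1 is a hypothesis that could be checked on DNA; no biological explanation was tested.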

How the results depend on the processing

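The removal of genes on X and Y and of 3 wrongly matched list members was chosen after seeing the data; all other alternatives were planned. Ezh2 stayed lower and called in all 3 comparisons under every alternative run. The 4 counts of changed genes stayed within 1.5 times under both scalings, the filter on level, the variance trend, array weights, averaged probe sets and the removal of X and Y genes. Similar counts did not mean the same genes. Of the 2000 called between hairpins, 1127 were called again after quantile normalization and 1502 with arrays shifted to one median. Of the 3033 for lymphomas against premalignant cells, 2791 and 2726 were called again. At least 2-fold changes numbered 517 for lymphomas against premalignant cells, 470 for shEzh2.781, 688 for shEzh2.556 and 242 between hairpins, and 299 genes changed so with both hairpins, fewer by construction. The fit of the 4 lymphomas as one group called 1091, as differences between hairpins then enter the spread. Leaving out 1 array gave 1721 to 2833 genes for lymphomas against premalignant cells, 1103 to 2048 for shEzh2.781, 1949 to 3669 for shEzh2.556, 718 to 2085 between hairpins and 782 to 1188 changed the same way with both; a lone array is then assumed to vary like the other groups. Called lists for lymphomas numbered 10 among genes above the median level, 0 with an estimated correlation and 11 with fry; between hairpins they numbered 5 after quantile normalization, 9 among genes above the median level, 0 with an estimated correlation and 0 with fry. Without the 3 wrongly matched members 19 and 16 lists were called, the metabolic MYC targets and T cell markers being added between hairpins. The cause was not tested. Ezh1, never called, turned from -0.04 to 0.0056 after quantile normalization and ranged from -0.0988 to 0.0197 with 1 array left out, and Eed, never called, ranged from -0.0115 to 0.196. The replicate number as a block called 2889, 2078, 3371 and 1783 genes in the 4 comparisons; the numbers do not pair the samples, as deviations of same-numbered arrays correlated across genes at -0.09, -0.12 and 0.06. Signal over background limits the genes near the floor.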

Other observations

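In all, 5 genes were below 7 in both premalignant arrays and above 9 in all 4 lymphoma arrays (log2 signal), bounds chosen after the values were seen. Among them were Cpn1 and Hepacam2, already given as large rises, and 2 others, the leukotriene receptor gene Cysltr1 and Nes, which encodes the intermediate filament nestin. Cysltr1 was 6.57 and 6.60 in premalignant cells and between 9.61 and 9.92 in the lymphomas, and Nes was 6.61 and 6.22 against 9.41 to 9.68. The opposite pattern held for Ear6, Marcks, Tes, Tet1 and Tmem132e, the last at 9.06 and 9.21 in premalignant cells and 6.77 to 6.90 in the lymphomas.

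Plasma cell and germinal centre lists were not called in either comparison, yet members moved in both directions. Slamf7 fell by 1.07 (SE 0.10) in lymphomas and Irf4 by 0.64 (SE 0.11), while Fkbp11 rose by 1.08 (SE 0.11) and Mzb1 by 0.76 (SE 0.09). Among germinal centre genes Lmo2 rose by 1.10 (SE 0.14), and Neil1 fell by 1.14 (SE 0.13) and Stap1 by 0.94 (SE 0.11). Lmo2 was 1.04 lower with shEzh2.781 than with shEzh2.556, as a difference of -1.04 (SE 0.16). Of the lists added after the data were seen, that of eosinophils held Ear6 and Prg2, whose falls had prompted it; 2 of the other 5 genes were lower in the lymphomas (median -0.31), against 4 of all 7 (median -1.28; 1 of the 7 was above 9 in both premalignant arrays). The 21 further erythroid genes had medians of -0.61 with shEzh2.781 and -0.15 with shEzh2.556, 5 of them above 9 in both premalignant arrays.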
